A study of Oryza sativa with 17 samples.

How the data were processed

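RNA from spikelets of 3 rice cultivars under 2 water treatments was measured on 17 Agilent 1-colour arrays, 1 array per sample. Per the labels' protocols, 50 ng of RNA was labelled with Cy3 by a low-input labelling kit. Groups and replicate numbers were taken from the sample labels. The labels give different plants per genotype and treatment.

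The deposited scanner files hold intensities per spot, with 62976 spots per array, of which 61657 were probe spots and 1319 control spots. Per the file headers they were made with Agilent Feature Extraction 11.5.1.1, while the submitters' processing notes name version 11.0. The processed intensity that the authors deposited is background-corrected by Feature Extraction and is not scaled between arrays, per the file headers. The deposited series table holds log2 values whose scale and centring are not given in the sources used here. Each probe had a median of 0 over the arrays, so the values were centred by probe. Decimal points that had been lost were restored behind the first digit (13.2% of values, with another 0.255% in exponent form). A value with more than 1 digit before its decimal point would come out too small by this rule. All 52901 probes matched the scanner files. Column medians ran from -0.0268 to 0.0303. Over 26092 probes the columns correlated with centred scanner values at r = 0.963 to 0.995, and with centred quantile-normalized values at r = 0.994 to 1. The lowest of the latter were those of the Wayrarem drought arrays. The direction was thus that of log2 signal; the absolute scale stays unknown because of the centring.

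Control spots were left out. Spots marked as outliers (at most 0.0811% of an array) were left out where the probe had another spot not so marked, and were kept otherwise. The spots of 8756 probes with 2 spots were averaged, and 44145 had 1 spot. Log2 processed signal minus the 75th percentile of each array was analysed. That percentile ran from 86.1 (Wayrarem drought replicate 1) to 266 (Wayrarem well-watered replicate 3), and the drought arrays of Wayrarem were dimmer than its well-watered ones, with a mean log2 percentile of 6.71 against 7.84. A probe entered when it was well above background on every array of at least 1 group, which kept 35095 loci with 1 probe each. The table of rice gene names given for this work holds none of the array's locus identifiers (0 of 52900 matched), so the gene lists and tissue marker lists fixed beforehand could not be tested. Positions are locus numbers within a chromosome, which follow gene order and are not base pairs. Windows of 2000 locus numbers took the place of windows in base pairs.

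Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 coefficient for each of 6 groups and 1 estimate of the spread per locus over all 17 arrays. Benjamini-Hochberg adjustment ran over loci within each of 12 contrasts, at a threshold of 0.05. Adjusted p-values in all parts come from limma unless Fisher's exact test or a permutation test is named. Fisher's exact test was two-sided for chromosomes and one-sided, for a higher share, for windows, so windows with a low share could not pass. It counts loci as independent, though all were read on the same 17 arrays and neighbouring loci may go together. Its p-values therefore do not measure variation between plants and may be too small. Loci were named by a rule set before the data were examined, the largest rises and falls past the threshold, with drought and well-watered arrays not overlapping for the drought responses (chance share 10% for 3 arrays against 3). Because no names could be attached, at most 2 in each direction are given per comparison, plus LOC_Os12g29330. Loci outside this rule were chosen after their values were seen. A locus not well above background on any array of the dimmer group is given as at least N-fold. There, the mean of the brighter group was set against the mean over the dimmer arrays of the higher of the probe's own signal and the lowest signal well above background. N allows for that floor alone and not for the SE or the choice of processing. It is thus not a lower limit on the change in transcript level.

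Files place the arrays on 4 slides, scanned in 4 sessions on 3 days. Slide 1 held 1 481-B drought and 1 Vandana drought array, and slide 2 held 2 481-B drought and 2 Wayrarem drought arrays. Slide 3 held 3 481-B well-watered, 2 Vandana drought and 1 Wayrarem drought array, and slide 4 held all well-watered arrays of Vandana and Wayrarem. No drought response could be measured within a slide.

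The calls were tested on simulated data with 35095 loci, 200 of them changed. In the drought comparison of 481-B, 19.4%, 86.6% and 90.9% of changes of 1, 2 and 3 on the log2 scale were recovered with 24 false calls, in that of Vandana 17.9%, 71.6% and 90.9% with 68 false calls, and in that of Wayrarem 16.4%, 68.7% and 90.9% with 0 false calls. For 481-B against Vandana under drought 17.9%, 67.2% and 93.9% were recovered, with 41 false calls. For the same cultivars when well-watered 17.9%, 80.6% and 95.5% were recovered, with 55 false calls. Within and between 481-B and Vandana, false calls were thus a larger share of all calls than the threshold is meant to allow. Adjusted p-values in these comparisons may therefore be too small. In the comparisons of level with Wayrarem there were 1 to 9 false calls.

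Alternatives set before the data were examined were quantile normalization, normexp background correction (offset 50) with quantile normalization, median scaling, filters on dim probes, fits of only the groups compared, the replicate number or slide as a block, array weights, the series table and leaving out each array. The mean signal named for normexp was absent from the files, and the median signal was used. Added after seeing the data were array brightness as a covariate, the Wayrarem drought arrays averaged, fits within a slide, 481-B drought replicate 3 and Vandana drought replicate 1 left out together, placing 481-B with the other water treatment, and the contrast averaged over water. Loci that separate the parents by a gap between all Wayrarem and all Vandana arrays were also a choice made after seeing the data. Gaps of 1, 2, 3 and 4 on the log2 scale were looked at, with all 5 Vandana arrays and with 4 (without drought replicate 1), before the gap of 2 was taken for the values given; the other gaps are given beside them.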

Results

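Transcript levels were measured in spikelets, the flower-bearing units of the panicle, of rice (Oryza sativa) sampled 35 days after sowing. Cultivars were the upland variety Vandana, the variety Way Rarem (labelled Wayrarem) and 481-B. By general background, 481-B is a line bred from a cross of Vandana with Way Rarem that carries the drought-yield locus qDTY12.1 of chromosome 12 from Way Rarem. Plants were either kept at field capacity (well-watered) or left to dry down from 75% of field capacity (drought). Each of the 6 groups held 3 arrays, except well-watered Vandana with 2 (replicates 2 and 3), which gave 17 arrays. The labels describe different plants per genotype and treatment in a randomized complete block layout with 3 replications.

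Each array carried 52901 probes, of which 52900 named a distinct locus and 1 named none. Between 56.7% (481-B drought replicate 2) and 72.8% (481-B well-watered replicate 1) of the probes were well above background on an array, and no probe spot was saturated. 35095 loci were well above background on every array of at least 1 group and were tested, and 26092 were so on all 17 arrays. The number of arrays per group limits the precision. Loci are given by the identifiers on the array, because no table used here pairs these identifiers with gene names, and gene lists such as dehydrins or heat shock proteins were therefore not tested. In every comparison an array signal does not separate transcript level from a sequence difference under the probe.

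The first principal component held 37.5% of the variance and set Wayrarem apart from Vandana and 481-B. The second held 21.7% and separated drought from well-watered Wayrarem, with drought arrays between -94.2 and -88.4 and well-watered ones between 103.5 and 113.2. The arrays of 481-B and Vandana lay between these, with 481-B drought replicate 3 at -85.3 closest to the Wayrarem drought arrays. The median SD between replicates was 0.39 on the log2 scale in 481-B drought and in well-watered Vandana, and it was smallest in Wayrarem drought, with 0.14. Between-array SD in Wayrarem drought was 1.20 times the noise between duplicate spots of 1 array, against 2.23 to 4.33 times in the other groups. 3 arrays correlated better with the other cultivar under the same water treatment than with their own group. For 481-B drought replicate 3 the mean r was 0.954 with Vandana against 0.941 with its own group. For Vandana drought replicate 1 it was 0.956 with 481-B against 0.941, and for Vandana well-watered replicate 3 it was 0.958 with 481-B against 0.950.

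**Figure D1:**
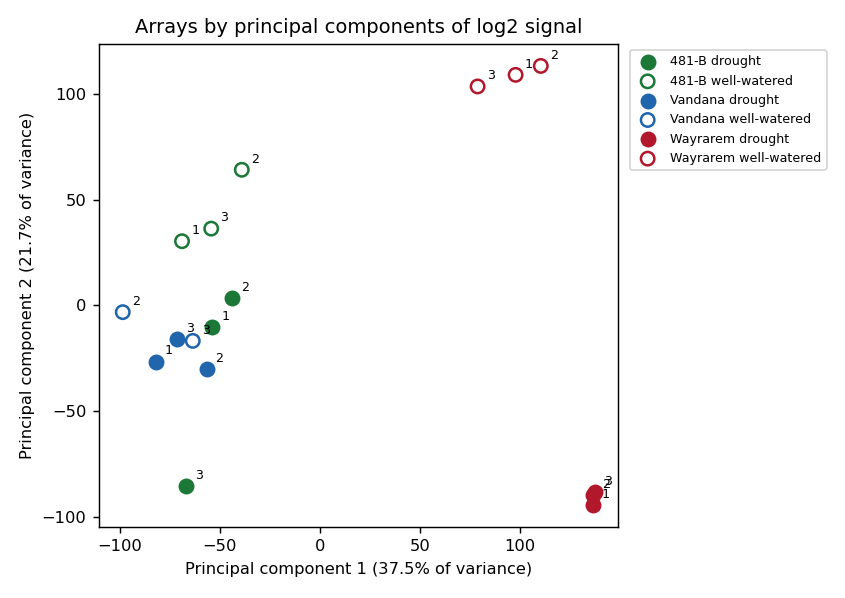
Scores of the 17 arrays on the first principal component (x axis, 37.5% of variance) and the second (y axis, 21.7% of variance) of log2 signal over 35095 loci; filled circles are drought arrays, open circles well-watered arrays, colours are cultivars and the digits are replicate numbers. The 3 Wayrarem drought arrays lie together at the lower right, and 481-B drought replicate 3 lies apart from its group at -85.3 on the second component.

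The response to drought was asked in each cultivar by setting its drought arrays against its well-watered arrays. Wayrarem responded at 12653 of the 35095 loci (36.1%) by limma at an adjusted p under 0.05, of which 7094 rose and 5559 fell, and 8370 changed at least 2-fold. With quantile normalization 6032 rose and 5770 fell, and with normexp and quantile normalization 5911 and 5665. The size of the excess of rises thus depended on the scaling. The median size of these changes was 1.22 on the log2 scale. LOC_Os02g07900 rose by 9.49 on the log2 scale (SE 0.61, adjusted p = 3.86e-07 by limma, n = 3 and 3). It was not well above background on any well-watered Wayrarem array, so its rise is given as at least 658-fold under the reported processing. Under alternatives the rise of LOC_Os02g07900 was as low as 4.82 on the log2 scale. LOC_Os04g45350 rose by 8.87 (SE 0.53, adjusted p = 2.05e-07 by limma), at least 295-fold. LOC_Os04g53300 changed by -7.14 (SE 0.56, adjusted p = 2.09e-06 by limma) and LOC_Os05g19910, well above background on 2 of 3 drought arrays, by -6.96 (SE 0.53, adjusted p = 1.54e-06 by limma). The chromosome with the smallest p was chromosome 3, where 34.3% of loci changed (Fisher's exact test, adjusted p = 0.150 over 12 chromosomes). All well-watered Wayrarem arrays lay on slide 4 and all drought arrays on slides 2 and 3, so slide and water could not be told apart within Wayrarem. Well-watered Vandana arrays shared slide 4, and Vandana's median change in Wayrarem's direction at these loci was 0.01 (quartiles -0.31 and 0.31). This argues against an effect of slide 4 common to both cultivars. With the 3 drought arrays, which differed little more than duplicate spots do, averaged to 1 sample, 2543 loci passed, and 4839 passed with array brightness as a covariate.

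In 481-B, 422 loci changed by limma at an adjusted p under 0.05, of which 286 rose and 136 fell, and 294 changed at least 2-fold. LOC_Os12g24020 rose by 4.56 on the log2 scale (SE 0.87, adjusted p = 0.0268 by limma, n = 3 and 3), at least 23.4-fold, since it was not well above background on any well-watered 481-B array. LOC_Os09g30458 rose by 4.33 (SE 0.96, adjusted p = 0.0462 by limma). LOC_Os08g01520, well above background on 1 of 3 drought arrays, changed by -4.41 (SE 0.90, adjusted p = 0.0355 by limma) and LOC_Os10g31420 by -3.95 (SE 0.61, adjusted p = 0.016 by limma). LOC_Os08g01520 was well above background on all Vandana arrays and on no Wayrarem array in either treatment, and its SD in 481-B drought was 2.56. A difference in parental level between the 481-B plants cannot be told apart from drought at this locus. The count rested on single arrays: it was 0 without 481-B well-watered replicate 2, 3 without well-watered replicate 1, 153 without well-watered replicate 3, 64 without drought replicate 1 and 110 without drought replicate 3. No slide held both treatments of 481-B. With slide as a fixed term 0 loci passed by limma. With slide as a random block 1398 passed, at an estimated correlation within slides of -0.0763. A correlation below 0 lowers the SE between slides and does not model a slide effect. This count, and the others with slide as a random block, therefore do not allow for such an effect.

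In Vandana no locus passed an adjusted p of 0.05 by limma, while 3712 of 35095 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0526 (n = 3 and 2). The count rested on single arrays here too. Without Vandana drought replicate 1 it was 1935, without Vandana well-watered replicate 3 it was 232, and without well-watered replicate 2 it was 3. The well-watered Vandana arrays lay on slide 4 and the drought arrays on slides 1 and 3, so slide and water could not be told apart; with slide as a random block 10 loci passed.

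**Figure D2:**
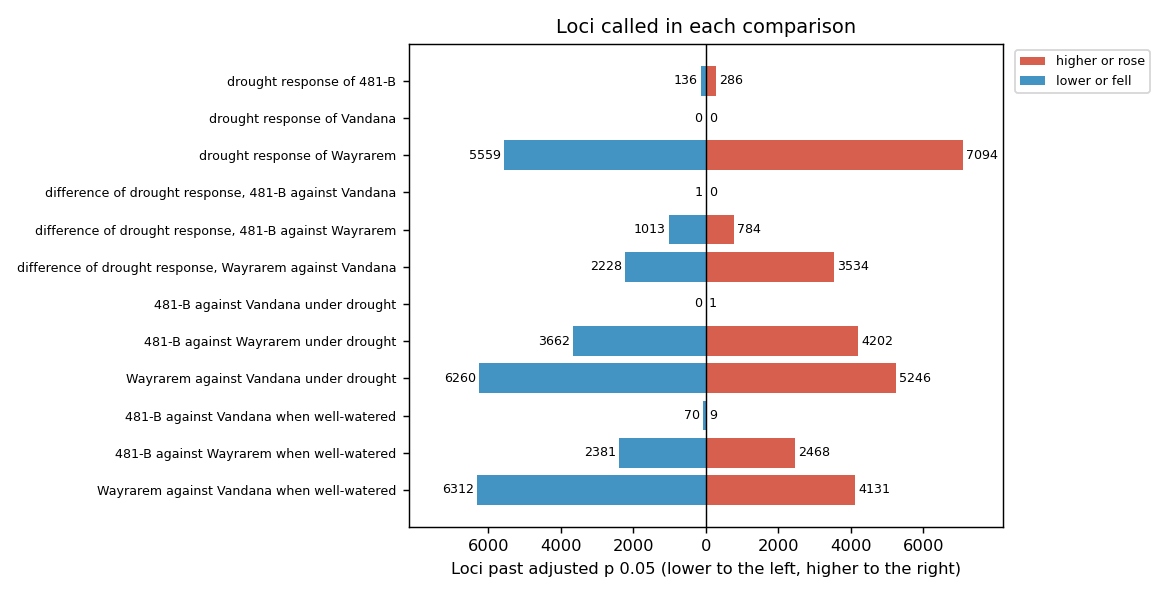
Numbers of loci past an adjusted p of 0.05 by limma (x axis) in each of the 12 comparisons (y axis); bars to the right count loci that rose or were higher in the cultivar named first, bars to the left those that fell or were lower. Wayrarem has 7094 and 5559 loci in its drought response, 481-B has 286 and 136, and Vandana has 0 and 0.

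Loci that changed in 481-B mostly moved the same way in Wayrarem. Of the 422 loci, 368 (87.2%) had the same sign in Wayrarem, and 280 passed the threshold in both in the same direction, 165 upward and 115 downward. Independent lists of these sizes would share 57.8 upward and 21.5 downward, and 21 loci passed in both with opposite signs. The cultivars share no arrays, but 2 drought arrays of each lay on slide 2, which held no well-watered array and no Vandana array, and the expected numbers take no account of a shared slide. Across the 35095 loci, which are not independent replicates, the log2 changes of 481-B and Wayrarem had a Pearson r of 0.505 and a Spearman rho of 0.522. For Vandana the r with Wayrarem was 0.0863; the difference between these correlations was not tested. At the 12653 loci of Wayrarem 83.4% had the same sign in 481-B and 51.0% in Vandana. With 481-B, Vandana's changes had an r of 0.210, and 361 of the 422 loci (85.5%) had the same sign. The shared count of 280 fell to 0 without 481-B well-watered replicate 2, 1 without well-watered replicate 1, 114 without well-watered replicate 3, 37 without drought replicate 1 and 71 without drought replicate 3. Without single Wayrarem arrays it was 145, 120 and 123 (drought replicates 1, 2 and 3) and 156, 156 and 172 (well-watered replicates 1, 2 and 3), and with slide as a random block it was 908.

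**Figure D3:**
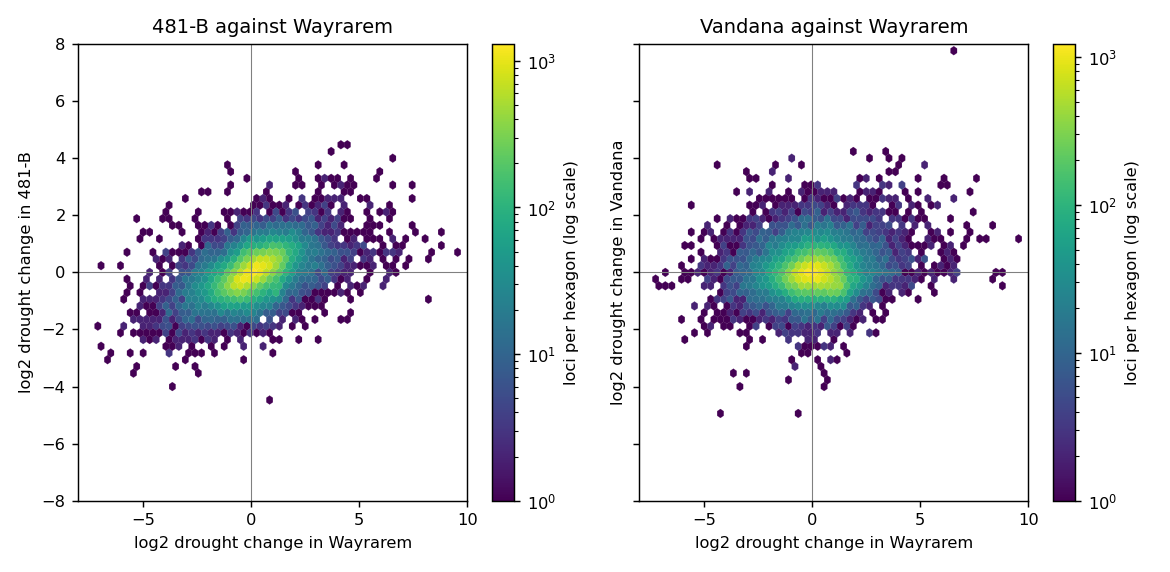
Log2 change under drought of the 35095 loci in Wayrarem (x axes) against that in 481-B (left, y axis) and in Vandana (right, y axis); colour counts loci per hexagon on a log scale. The cloud is tilted for 481-B (r = 0.505) and nearly level for Vandana (r = 0.0863).

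Whether the cultivars responded differently was tested as the difference of their log2 drought changes. Wayrarem and Vandana differed at 5762 loci by limma, 3534 with the more positive change in Wayrarem and 2228 with the more negative, and 5266 differed at least 2-fold. LOC_Os04g45350 (9.29, SE 0.80, adjusted p = 3.71e-05 by limma) and LOC_Os04g32680 (8.66, SE 0.98, adjusted p = 2.71e-04 by limma) had a more positive change in Wayrarem. LOC_Os01g28450 (-8.31, SE 1.24, adjusted p = 0.00161 by limma) and LOC_Os06g29730 (-7.96, SE 1.38, adjusted p = 0.00366 by limma) had a more negative one. These sizes are of array signal and partly rest on dim groups: LOC_Os04g45350 was well above background on 3 of 3 Wayrarem drought arrays and on no well-watered Wayrarem or Vandana array, LOC_Os06g29730 on 0 of 3 Wayrarem drought arrays, LOC_Os04g32680 on 1 of 3 well-watered Wayrarem and 2 of 3 Vandana drought arrays, and LOC_Os01g28450 on 2 of 3 Wayrarem drought arrays. On chromosome 11, 18.5% of the tested loci differed and on chromosome 3 14.3%, against 16.4% over all (Fisher's exact test, adjusted p = 0.0374 and 0.00105). With slide as a fixed term 2107 loci passed, with array brightness as a covariate 1298 and with the Wayrarem drought arrays averaged 440. Leaving out Vandana drought replicate 2 or 3 gave 3791 or 3594, Vandana well-watered replicate 3 gave 3720, Wayrarem drought replicates 1, 2 and 3 gave 3762, 3512 and 3593, and Wayrarem well-watered replicate 3 gave 3735.

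481-B and Wayrarem differed in their response at 1797 loci by limma, 784 with the more positive change in 481-B and 1013 with the more negative. With quantile normalization these were 945 and 949, and with normexp and quantile normalization 1179 and 1520. LOC_Os10g19912 (7.14, SE 0.88, adjusted p = 5.67e-04 by limma) and LOC_Os11g14880 (6.99, SE 1.34, adjusted p = 0.00874 by limma) were more positive in 481-B. LOC_Os05g33150 (-9.18, SE 1.05, adjusted p = 3.08e-04 by limma) and LOC_Os02g07900 (-8.76, SE 0.86, adjusted p = 9.02e-05 by limma) were more negative. These sizes too partly rest on dim groups: LOC_Os10g19912 and LOC_Os11g14880 were well above background on 0 of 3 Wayrarem drought arrays, LOC_Os05g33150 on 0 of 3 drought and 1 of 3 well-watered 481-B arrays, and LOC_Os02g07900 on 1 of 3 drought and 0 of 3 well-watered 481-B arrays and 0 of 3 well-watered Wayrarem arrays. The count was 3295 without 481-B drought replicate 3 and 1110 without 481-B well-watered replicate 3. It was 1046, 991 and 968 without Wayrarem drought replicate 1, 2 or 3, and 1162 and 1080 without Wayrarem well-watered replicate 1 or 3. With slide as a random block 2967 loci passed, and 192 with the Wayrarem drought arrays averaged.

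481-B and Vandana differed in their response at 1 locus by limma, with 3600 at an unadjusted p under 0.05. LOC_Os08g02180 had a more negative change in 481-B than in Vandana, by -3.22 on the log2 scale (SE 0.39, adjusted p = 0.0411 by limma). It lay at -6.00 under drought and -3.63 when well-watered in 481-B, at -4.20 and -5.05 in Vandana, and at -6.17 and -3.62 in Wayrarem, relative to the 75th percentile of each array. It was well above background on 0 of 3 drought and 3 of 3 well-watered arrays of 481-B, and on 1 of 3 drought and 0 of 2 well-watered arrays of Vandana, so its size partly rests on dim groups. With the replicate number as a block 0 loci passed by limma (smallest adjusted p = 0.237, 3524 at an unadjusted p under 0.05). The count was 64 without Vandana well-watered replicate 3, 7 without Vandana well-watered replicate 2 and 6 without Vandana drought replicate 1. It was 0 without each of 481-B drought replicates 1, 2 and 3, 481-B well-watered replicate 2 and Vandana drought replicates 2 and 3, and LOC_Os08g02180 also missed the threshold without Vandana well-watered replicate 2 and with normexp and quantile normalization, where its value was -0.33 and a different locus passed. It missed the threshold as well without a filter on dim probes, with only the groups compared, with array weights and with array brightness as a covariate, and it was not tested with probes well above background on all arrays.

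In the reported fit the parents differed most in level. With array weights, when well-watered, fewer loci differed between the parents than between 481-B and Wayrarem. Under drought 11506 loci differed between Wayrarem and Vandana by limma, 5246 higher and 6260 lower in Wayrarem, and 7545 differed at least 2-fold. When well-watered 10443 differed, 4131 higher and 6312 lower in Wayrarem, and 7694 at least 2-fold. Under drought LOC_Os04g27310 (10.47, SE 0.66, adjusted p = 8.15e-08 by limma) and LOC_Os11g22080 (10.36, SE 0.67, adjusted p = 1.1e-07 by limma) were higher in Wayrarem. LOC_Os07g04270 was lower in Wayrarem (SE 2.61 on the log2 scale, adjusted p = 0.0101 by limma), where it was well above background on 1 of 3 drought arrays, and LOC_Os01g71590 (-8.72, SE 0.22, adjusted p = 9.98e-12 by limma) at least 215-fold lower. When well-watered, LOC_Os01g56830 (9.03, SE 0.35, adjusted p = 9.94e-10 by limma) was at least 260.5-fold higher in Wayrarem, and LOC_Os12g31880 (9.51, SE 2.53, adjusted p = 0.0127 by limma) at least 324-fold higher. LOC_Os01g58035 (-11.12, SE 0.75, adjusted p = 2.24e-07 by limma) was at least 1761-fold lower, and LOC_Os07g04270 (-11.11, SE 2.92, adjusted p = 0.012 by limma) at least 1781-fold lower. At LOC_Os07g04270 and LOC_Os12g31880 the spread that sets the SE came from 481-B, with an SD of 6.17 and 5.11 under drought against 0.23 and 1.04 in Vandana, and each was well above background on 2 of 3 481-B arrays in either treatment. Without Vandana well-watered replicate 2 the well-watered count was 6410. With slide as a fixed term 6978 loci passed under drought and 9712 when well-watered; within slide 3 alone, with 1 Wayrarem drought array and the spread taken from the other groups of that slide, 1069 passed under drought and within slide 4 alone 8352 when well-watered. With the Wayrarem drought arrays averaged 3376 passed under drought.

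Chromosome 11 had the highest and chromosome 3 the lowest share of loci at which the parents differed in both treatments. Under drought 37.6% of the tested loci of chromosome 11 differed (Fisher's exact test, adjusted p = 5.87e-06 over 12 chromosomes) and 30.1% of those of chromosome 3 (adjusted p = 7.57e-04), against 32.8% over all; chromosome 9 was also high (35.4%, adjusted p = 0.0236) and chromosomes 4 and 10 low (30.6% and 30.1%, adjusted p = 0.0205 and 0.0236). When well-watered the shares were 32.8% on chromosome 11 (adjusted p = 0.00552), 32.7% on chromosome 12 (adjusted p = 0.00552) and 27.1% on chromosome 3 (adjusted p = 9.18e-04), against 29.8% over all.

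481-B also differed widely from Wayrarem. Under drought 7864 loci differed by limma, 4202 higher and 3662 lower in 481-B, and when well-watered 4849 differed, 2468 higher and 2381 lower. Under drought LOC_Os06g49930 (8.84, SE 0.41, adjusted p = 4.81e-09 by limma) was at least 298-fold and LOC_Os02g27594 (8.65, SE 0.22, adjusted p = 1.23e-11 by limma) at least 187-fold higher in 481-B. LOC_Os04g27310 (-10.50, SE 0.66, adjusted p = 8.45e-08 by limma) was lower in 481-B, and LOC_Os05g33150 (-10.20, SE 0.74, adjusted p = 3.81e-07 by limma) at least 729.8-fold lower. When well-watered LOC_Os01g58035 (10.22, SE 0.67, adjusted p = 1.35e-07 by limma) was at least 944-fold and LOC_Os03g43100 (SE 0.31, adjusted p = 8.18e-11 by limma) at least 1018-fold higher in 481-B. LOC_Os01g56830 (-9.47, SE 0.31, adjusted p = 1.44e-10 by limma) was at least 441-fold and LOC_Os06g06490 (-9.43, SE 0.96, adjusted p = 1.21e-05 by limma) at least 481-fold lower in 481-B. Chromosome 11 again had the highest share and chromosome 3 the lowest, with 26.2% and 19.3% under drought (Fisher's exact test, adjusted p = 6.58e-05 and 5.99e-06) and 17.6% and 10.9% when well-watered (adjusted p = 6.35e-07 and 8.73e-08). Chromosome 9 was also high under drought (25.3%, adjusted p = 0.00644), and when well-watered chromosomes 6 and 7 were high (15.5% and 16.2%, adjusted p = 0.0134 and 7.14e-04) and chromosome 4 low (11.7%, adjusted p = 7.14e-04). Within slide 2 alone 2459 loci passed under drought, with slide as a fixed term 6068 and with the Wayrarem drought arrays averaged 2404. No slide held well-watered arrays of both, and without 481-B well-watered replicate 3 the well-watered count was 2871 and without Wayrarem well-watered replicate 2 it was 2903.

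Between 481-B and Vandana few loci passed in the reported fit. With array weights, an alternative set beforehand, far more passed under drought, as given with the other alternatives below. Under drought 1 locus differed by limma, with 2338 at an unadjusted p under 0.05. LOC_Os12g16480 on chromosome 12 was higher in 481-B by 3.07 on the log2 scale (SE 0.34, adjusted p = 0.0135 by limma, n = 3 and 3). It lay at -0.62 in 481-B, at -0.74 in Wayrarem and at -3.69 in Vandana. The count was 181 without Vandana drought replicate 1, 27 without 481-B drought replicate 3, 2 without 481-B drought replicate 2, and 0 without 481-B drought replicate 1 or Vandana drought replicate 2 or 3. It was 3950 without both 481-B drought replicate 3 and Vandana drought replicate 1, the arrays that correlated better with the other cultivar, an alternative added after seeing the data. With slide as a fixed term 0 loci passed by limma, and also 0 with the replicate number as a block (smallest adjusted p = 0.0568, 2145 at an unadjusted p under 0.05). LOC_Os12g16480 also missed the threshold with normexp and quantile normalization and with only the groups compared.

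When well-watered 79 loci differed between 481-B and Vandana by limma, 9 higher and 70 lower in 481-B, with 6806 at an unadjusted p under 0.05. The share that was higher was 11.4%, and it was 22.3% with quantile normalization and 22.7% with normexp and quantile normalization. LOC_Os06g32350 (3.40, SE 0.62, adjusted p = 0.0443 by limma) and LOC_Os06g32355 (3.26, SE 0.55, adjusted p = 0.0355 by limma), neighbours on chromosome 6, were higher in 481-B. LOC_Os10g24170 (-4.85, SE 0.81, adjusted p = 0.0355 by limma) was at least 19.2-fold lower in 481-B, and LOC_Os06g20970, well above background on 1 of 3 well-watered 481-B arrays, was lower too (-3.87, SE 0.55, adjusted p = 0.0228 by limma). The count was 1637 without Vandana well-watered replicate 3, 229 without 481-B well-watered replicate 1, 24 without Vandana well-watered replicate 2, 1 without 481-B well-watered replicate 2 and 0 without 481-B well-watered replicate 3. No slide held well-watered arrays of both cultivars, and with slide as a random block 1050 loci passed. The simulation of this comparison, with 200 changed loci, gave 55 false calls, a larger share of its calls than the threshold is meant to allow.

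The level of 481-B against Vandana averaged over both water treatments was compared after seeing the data. 36 loci differed by limma, 11 higher and 25 lower in 481-B, with 6585 at an unadjusted p under 0.05. LOC_Os12g16130 was higher in 481-B by 3.46 on the log2 scale (SE 0.58, adjusted p = 0.0449 by limma) and LOC_Os12g16480 by 2.77 (SE 0.26, adjusted p = 0.00141 by limma). LOC_Os06g20970 (-3.37, SE 0.37, adjusted p = 0.00608 by limma) and LOC_Os12g28250 (-3.15, SE 0.51, adjusted p = 0.0395 by limma) were lower. 6 of the 36 lay on chromosome 12 (16.7%, against 6.60% of tested loci; Fisher's exact test p = 0.029, adjusted p = 0.314 over 12 chromosomes). At these 6 the median position of 481-B between Vandana (0) and Wayrarem (1) was 0.932 (from 0.685 to 1.17). At the other 30 loci it was 0.956, with a far wider range from -2.43 to 69.1. The count was 4321 without 481-B drought replicate 3, 2036 without Vandana well-watered replicate 3, 619 without Vandana drought replicate 1 and 224 without 481-B well-watered replicate 1. It was 19 without Vandana well-watered replicate 2, 12 and 7 without 481-B drought replicates 2 and 1, 8 and 5 without Vandana drought replicates 3 and 2, and 6 and 5 without 481-B well-watered replicates 2 and 3.

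**Figure D4:**
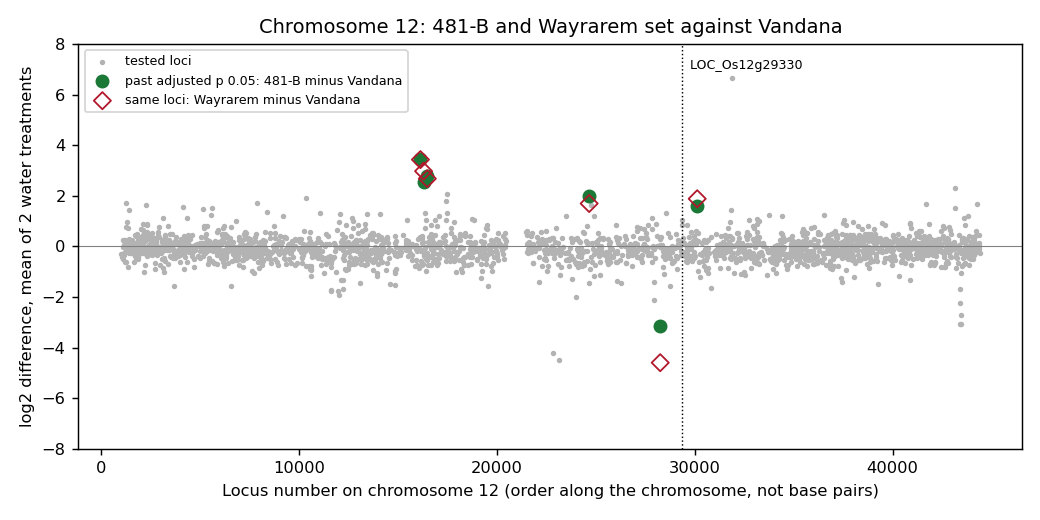
Log2 differences averaged over the 2 water treatments (y axis) along chromosome 12 by locus number (x axis, order along the chromosome and not base pairs); grey points are 481-B minus Vandana at all tested loci, green circles the 6 loci past an adjusted p of 0.05 by limma, and red diamonds Wayrarem minus Vandana at the same 6 loci. At each of the 6, Wayrarem differs from Vandana in the same direction as 481-B, and the dotted line marks LOC_Os12g29330.

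Where 481-B stood between its parents was measured at the 2545 loci at which Wayrarem and Vandana differed at least 2-fold in the same direction in both water treatments, each at an adjusted p under 0.05 by limma. Wayrarem was higher at 1027 and lower at 1518. 481-B lay nearer Vandana at 2272 of them and nearer Wayrarem at 273 (10.7%). On a scale with Vandana at 0 and Wayrarem at 1 its median position was 0.17 (upper quartile 0.37). That median was 0.098 without Vandana well-watered replicate 2 and 0.265 without Vandana well-watered replicate 3. With probes well above background on all arrays it was 0.267. In 50 simulations in which 481-B had the level of Vandana, 0.914% of loci came out nearer Wayrarem on average, and at most 1.26%. These drew independent noise with the same spread in all groups. With noise scaled to the spread of each group, a further simulation gave 1.69%. Neither holds deviations that the loci of an array share, so they do not settle whether 10.7% departs from the level of Vandana. Chromosome 3 had the highest share nearer Wayrarem, 39 of 188 loci (20.7%; Fisher's exact test, adjusted p = 2.82e-04 over 12 chromosomes), chromosome 12 had 15.4% (26 of 169, adjusted p = 0.210) and chromosome 11 had 5.41% (14 of 259, adjusted p = 0.0168). None of 317 windows of 2000 locus numbers passed a one-sided Fisher's exact test for a higher share (smallest adjusted p = 1). The share was 23.5% without 481-B drought replicate 3, 21.3% without Vandana well-watered replicate 3, 17.9% without 481-B well-watered replicate 1 and 5.41% without Vandana well-watered replicate 2. The share of chromosome 3 was 40.9%, 35.3%, 32.2% and 11.46% in these 4 leave-outs, in that order. That of chromosome 12 was 24.1%, 22.2%, 18.1% and 7.14%. Over all chromosomes the share was 5.04% with the Wayrarem drought arrays averaged. With parental differences taken under drought and 481-B placed when well-watered it was 15.0% over 7545 loci (18.8% on chromosome 3), and with the treatments exchanged it was 4.13% over 7694 loci (4.16% on chromosome 3). By single 481-B array the share ran from 5.54% (drought replicate 3) to 38.9% (well-watered replicate 2).

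LOC_Os12g29330, a NAM transcription factor gene of the qDTY12.1 region, was followed whatever its values. Its drought change was -1.08 on the log2 scale in 481-B (SE 0.51, adjusted p = 0.29 by limma), -0.20 in Vandana (SE 0.57, adjusted p = 0.926) and -0.64 in Wayrarem (SE 0.51, adjusted p = 0.347), and none passed. When well-watered LOC_Os12g29330 was higher in Wayrarem than in Vandana by 1.63 (SE 0.57, adjusted p = 0.0456 by limma), and under drought the difference was 1.19 (SE 0.51, adjusted p = 0.0901). LOC_Os12g29330 in Wayrarem against Vandana when well-watered missed the threshold without Vandana well-watered replicate 2 (adjusted p = 0.261 by limma) and without Wayrarem well-watered replicate 1, 2 or 3 (adjusted p = 0.094, 0.0957 and 0.0795). It also missed it by limma with quantile normalization (adjusted p = 0.0562), the series table (0.056), no filter on dim probes (0.0702), the replicate number as a block (0.0654), slide as a fixed term (0.0508) and array brightness as a covariate (0.0963). For 481-B against Vandana the difference was 1.47 when well-watered (SE 0.57, adjusted p = 0.183 by limma) and 0.60 under drought (SE 0.51, adjusted p = 0.825). The mean level in 481-B was 0.96 (SD 0.40, n = 3) when well-watered and -0.11 (SD 1.31, n = 3) under drought, relative to the 75th percentile.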

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

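Tests of slide for the Wayrarem response and the spread, both tests of the label swap, of the spread over chromosomes and of the Wayrarem segment were chosen after the results were seen, and the splits and the slide test for 481-B against Vandana averaged over water belong to a contrast that was itself chosen so; the others were set beforehand. The label swap was tested by a median position, which left it open, and then by linked loci, a test picked with its values at a gap of 2 on the log2 scale already seen; the other gaps looked at are given with it.

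Differences of drought response between cultivars passed a test of the difference itself. By limma 1797 loci did so for 481-B against Wayrarem, among them LOC_Os10g19912 (7.14), LOC_Os11g14880 (6.99), LOC_Os05g33150 (-9.18) and LOC_Os02g07900 (-8.76), as log2 differences. 5762 loci did so for Wayrarem against Vandana, among them LOC_Os04g45350 (9.29), LOC_Os04g32680 (8.66), LOC_Os01g28450 (-8.31) and LOC_Os06g29730 (-7.96). For 481-B against Vandana it was 1 locus, LOC_Os08g02180 (-3.22). Each of these loci was not well above background on at least 1 array of the groups compared, so the sizes are of array signal. For 481-B against Wayrarem 8 of 100 splits of the arrays drawn from 200 gave as many loci, and the highest other gave 9855, several times the real count. That split exchanged the water labels of all Wayrarem arrays, 481-B drought replicate 2 and 481-B well-watered replicate 3. It thus holds Wayrarem's own response against mixed 481-B arrays, so its count does not point to a structure of the samples. All 8 kept the Wayrarem arrays apart by water and so carry Wayrarem's own response; the splits thus leave undecided whether chance can be excluded.

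Other splits were too few for a share under 0.05 in the comparisons of 3 arrays with 3, which have 10 splits each. For the drought response of 481-B 1 of 10 splits gave as many loci (422 against 11 in the highest other), and for that of Wayrarem 1 of 10 (12653 against 1). For 481-B against Wayrarem under drought it was 1 of 10 (7864 against 2) and when well-watered 1 of 10 (4849 against 0), and for Wayrarem against Vandana under drought 1 of 10 (11506 against 0). For 481-B against Vandana under drought 3 of 10 splits gave as many loci as the real 1, and the highest gave 5750. For 481-B against Vandana averaged over water 13 of 100 splits drawn from 200 did, so chance cannot be excluded, with a highest count of 7483 against 36. Both highest splits exchanged 481-B drought replicate 3 with Vandana drought replicate 1, which points to a structure of the samples.

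Wayrarem responded to drought at 12653 loci while its well-watered arrays shared slide 4 with those of Vandana. At these loci the median change of Vandana in Wayrarem's direction was 0.895% of Wayrarem's (0.01 against 1.22, quartiles of Vandana -0.31 and 0.31), and between -8.15% and 10.1% without any 1 Vandana array, which argues against an effect of slide 4 common to both cultivars. With array brightness as a covariate the median change was 79.2% of its size (0.97 against 1.22), and 4303 of the 12653 loci still passed while the median SE grew from 0.29 to 0.36; this argues against brightness as the whole cause, though a part may remain. A shared origin of the 3 drought arrays, whose spread was 1.20 times the spot noise, stays open, and a response of the cultivar to drought is the hypothesis the design names.

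Replicates of 481-B and Vandana differed more than those of Wayrarem. The well-watered groups of these cultivars, each on 1 slide, had a median SD at least 1.98 times that of Wayrarem drought on 2 slides. A difference between slides cannot enter the spread of arrays that share 1 slide. Against well-watered Wayrarem on slide 4, the ratio was 1.77 for Vandana, on the same slide, and 1.28 for 481-B, on slide 3. A noisier slide is thus argued against for well-watered Vandana and stays open for well-watered 481-B. The drought groups lay on 2 slides each, and slide stays open for them. Brightness stays open: over 11 arrays the within-group deviations along the first residual component correlated with those of brightness at r = 0.203 (exact permutation p = 0.620 over 432 orders, Spearman rho 0.182, p = 0.655), and r was 0.625 without the 2 arrays farthest out. A swap of the labels of 481-B drought replicate 3 and Vandana drought replicate 1 stays open: between Vandana (0) and 481-B (1) they had a median position of 0.291 and 0.636 at 13 loci chosen on the other arrays, with 0.111 and 0.466 at 92 loci of a smaller gap, and at linked loci at which most other 481-B arrays had Wayrarem's level they had it at 4 and 0 of 9 (2 and 0 of 7, and 2 and 0 of 2, at gaps of 3 and 4), which goes against a swap, but at 9 and 5 of 31 at a gap of 1, which does not. Differences between plants, in stage or in genotype, may contribute and were not tested here as a cause of the spread.

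6 of the 36 loci at which 481-B differed from Vandana lay on chromosome 12. Their number there could be chance, with an adjusted p of 0.314 over 12 chromosomes. On slide 1, with 1 array of each cultivar, their median difference was 89.2% of the pooled one (2.37 against 2.66, same direction at 6 of 6). At the 6 loci ranked without slide 1 it was 62.3% (1.87 against 2.99). Within slide 3 the median at the called loci was 1.78, for well-watered 481-B against drought Vandana arrays. Differences within a slide are not differences between slides. But slide 1 rests on 1 array of each cultivar and slide 3 mixes in water, so a part from slide stays open. A Wayrarem segment in 481-B is the biological hypothesis, and the median position of 0.932 (from 0.685 to 1.17) lay near Wayrarem's level. The loci of other chromosomes had a median of 0.956, but ran from -2.43 to 69.1. That median therefore does not place them at Wayrarem's level as a set. What keeps the segment open is that the position was taken at loci chosen for their difference.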

How the results depend on the processing

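Alternatives added after seeing the data were array brightness as a covariate, the averaged Wayrarem drought arrays, fits within a slide, the pair of arrays left out together, the exchanged water treatments and every alternative for 481-B against Vandana averaged over water; the others were set beforehand. Of 288 values under alternatives for 14 counts, 150 stayed within 1.5 times and 138 did not. The share of parental differences nearer Wayrarem ran from 4.13% to 26.5%. Quantile normalization, median scaling and the series table moved no count past 1.5 times. A count that stayed does not mean the same loci: with normexp and quantile normalization 1 locus again passed for the difference of 481-B and Vandana, but it was not LOC_Os08g02180 and its difference had the other sign. The largest changes named make 42 pairs of locus and comparison, some loci being named in more than 1 comparison. Of 825 values of these pairs under alternatives, 712 kept direction and threshold, 113 kept only direction and 0 reversed. Sizes moved more. On the log2 scale the drought rise in Wayrarem ran from 4.82 to 9.76 at LOC_Os02g07900 and from 3.73 to 8.98 at LOC_Os04g45350. For Wayrarem against Vandana under drought, LOC_Os04g27310 ran from 1.27 to 11.1 and LOC_Os01g71590 from -9.06 to -3.98. The folds given as at least N thus hold only for the reported processing. No scaling shifted the median of all loci by over 0.1. The cause of the changes below was not tested, and signal over background limits the dim loci.

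Normexp with quantile normalization gave 831 loci for the drought response of 481-B, 5 for that of Vandana, 2699 for the difference of 481-B and Wayrarem, 516 shared by both responses, and for 481-B against Vandana 0 under drought, 353 when well-watered and 72 averaged. Without a filter on dim probes these were 40 for 481-B, 0 for the difference of 481-B and Vandana, 1134 for that of 481-B and Wayrarem, 24 shared, and 16 and 5 for 481-B against Vandana when well-watered and averaged. With probes well above background on all arrays they were 0, 244 and 3136 for the difference of 481-B and Vandana, 481-B against Vandana when well-watered and 481-B against Wayrarem when well-watered. Fitting only the groups compared takes the spread from their arrays alone. The median SD was 0.14 and 0.22 in the Wayrarem groups against 0.28 to 0.39 in those of 481-B and Vandana. These fits gave 0 for 481-B, 19406 for Wayrarem, 3152 for the difference of 481-B and Wayrarem, 0 shared, and by limma 0 for each comparison of 481-B with Vandana and their difference. The reported calls within and between 481-B and Vandana thus rest on a spread pooled with that of Wayrarem.

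Replicate numbers were not taken to pair the samples, since the labels do not tie them to the blocks of the layout. Deviations of same-numbered arrays correlated at -0.35 to 0.40 (median -0.0241, 8 of 40 pairs over 0.1). Those values do not settle whether the numbers are blocks. With the replicate block 259 loci passed for 481-B, 171 were shared, 41 passed for 481-B against Vandana when well-watered, and 0 under drought and for their difference; other counts stayed within 1.5 times. Slide as a fixed term gave 0 for 481-B, 2107 for the difference of Wayrarem and Vandana, and under drought 0 for 481-B against Vandana and 6978 for Wayrarem against Vandana; responses of Vandana and Wayrarem could not be estimated. Slide as a random block, with an estimated correlation of -0.0763, gave 1398 for 481-B, 10 for Vandana, 2967 for the difference of 481-B and Wayrarem, 908 shared and 1050 for 481-B against Vandana when well-watered. With a correlation below 0 these counts do not allow for a slide effect. Within slide 2, 2459 passed for 481-B against Wayrarem under drought, and within slide 3, which held 1 Wayrarem drought array, 1069 for Wayrarem against Vandana, the lone array being assumed to vary like the other groups of that slide.

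Array weights (0.158 to 7.07) gave 7981 for 481-B, 22155 for Wayrarem, 0 and 13405 for the differences of 481-B with Vandana and Wayrarem, and 5000 shared. Under drought they gave 15097 for 481-B against Vandana, 22104 for 481-B against Wayrarem and 22414 for Wayrarem against Vandana. When well-watered they gave 0, 12368 and 6844, and 5721 for 481-B against Vandana averaged. With brightness as a covariate 4839 passed for Wayrarem, 0 for the difference of 481-B and Vandana, 1298 for that of Wayrarem and Vandana, and 122 and 73 for 481-B against Vandana when well-watered and averaged. With the Wayrarem drought arrays averaged 2543 passed for Wayrarem, 192 and 440 for its differences with 481-B and Vandana, 2404 and 3376 against them under drought, and 11 were shared.

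Leaving out 1 array gave 0 to 514 loci for 481-B (0 without well-watered replicate 2), 0 to 1935 for Vandana (1935 without drought replicate 1) and 9386 to 9761 for Wayrarem. It gave 0 to 64, 968 to 3295 and 3512 to 8447 for the differences of 481-B and Vandana, 481-B and Wayrarem, and Wayrarem and Vandana. It gave 0 to 181 and 0 to 1637 for 481-B against Vandana, 5474 to 8935 and 2871 to 4025 for 481-B against Wayrarem, and 8131 to 12203 and 6410 to 10001 for Wayrarem against Vandana, under drought and when well-watered. It gave 5 to 4321 for the average over water, 0 to 394 shared loci and 5.41% to 23.5% of parental differences nearer Wayrarem. Without both 481-B drought replicate 3 and Vandana drought replicate 1 there were 928 loci for 481-B, 4047 for Vandana, 778, 5618 and 10928 for these differences, 3950 for 481-B against Vandana under drought, 7662 averaged, 588 shared and 26.5% nearer Wayrarem.

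LOC_Os12g29330 changed sign where it had not passed the threshold. With slide fixed the difference of Wayrarem and Vandana was 0.0866. Leaving out arrays gave -0.88 to 0.0017 for that difference (highest without Vandana well-watered replicate 2), -1.003 to 0.28 for that of 481-B and Wayrarem and -1.16 to 0.13 for 481-B against Wayrarem under drought (both highest without 481-B drought replicate 3, and 0.28 and 0.13 also without both arrays), -0.64 to 0.24 for the response of Vandana (above 0 without drought replicate 3, 0.0035, and well-watered replicate 3), and -1.44 to 0.23 for the difference of 481-B and Vandana (0.23 without both arrays). Testing every probe by itself equals the reported fit, and the gene list tests were not run.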

Other observations

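All tests and groupings of loci in this part were chosen after the results were seen. Some loci were well above background in all arrays of 1 parent and in none of the other. 181 were so in all 6 Wayrarem arrays and in none of 5 Vandana arrays, and of these 109 were in no 481-B array, 71 in some and 1 in all 6. That locus was LOC_Os12g24659 on chromosome 12. In the other direction 234 were well above background in all Vandana and no Wayrarem arrays, 43 of them on chromosome 11, and of these 164 were so in all 481-B arrays, 70 in some and 0 in none. By water treatment, 366 loci were well above background in all drought and no well-watered arrays of Wayrarem and 1009 the other way round. In 481-B these were 14 and 218, and in Vandana 129 and 145. In Wayrarem and 481-B these counts run opposite to the loci that rose and fell by limma (7094 and 5559, 286 and 136). Drought arrays were dimmer in both, with 75th percentiles of 86.1 to 118 against 204.5 to 266 in Wayrarem and of 87.4 to 189 against 147 to 249 in 481-B, which bears on what counts as well above background.

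The loci at which the parents differed were denser in some windows of 2000 locus numbers. Of 323 windows 10 passed a one-sided Fisher's exact test for a higher share, and 6 of them lay on chromosome 11. In the window of chromosome 11 with the smallest p, 19 of 96 tested loci differed (19.8%, adjusted p = 0.0113), against 7.25% over the genome.

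481-B arrays did not all stand on the same side between the parents. At 378 loci every Wayrarem array was at least 2 on the log2 scale from every Vandana array. At 337 of them no 481-B array had passed the middle of that gap towards Wayrarem, at 40 some had, and at 1, LOC_Os06g20970, all 6 had. The count per array was 23, 10 and 12 for drought replicates 1, 2 and 3 and 7, 21 and 21 for well-watered replicates 1, 2 and 3. LOC_Os07g04270 was at -6.66 and -5.07 in drought replicate 1 and well-watered replicate 3 and between 4.02 and 4.09 in the other 4, while Vandana lay between 4.67 and 5.51 and Wayrarem between -7.12 and -2.76. On chromosome 12, from LOC_Os12g22810 to LOC_Os12g28720, 4 such loci had the level of Wayrarem in the same 4 arrays (drought replicates 1 and 3, well-watered replicates 2 and 3). A candidate explanation is that the 481-B plants carried different parental segments. Neighbouring loci then share the same arrays, and 5 neighbouring pairs did, against 0.283 on average and at most 3 over 10000 shuffles of the loci (permutation p = 1e-04, the smallest they can give). At gaps of 1, 3 and 4, also looked at, 18, 3 and 2 pairs were found against 4.38, 0.0697 and 0.0373 on average (permutation p = 1e-04 each, the smallest they can give); with 4 Vandana arrays (without drought replicate 1) the pairs were 25, 9, 8 and 2 at gaps of 1 to 4 (p at most 2e-04). Neighbouring loci can also be near-identical copies read by like probes. 4 further loci between LOC_Os12g23150 and LOC_Os12g28250 had the level of Vandana in all 481-B arrays. LOC_Os12g24659, also in that stretch, was instead well above background in all 481-B and Wayrarem arrays and in no Vandana array. Signal is not genotype, so these loci do not decide whether 1 unbroken segment accounts for the chromosome 12 loci. Expression differences between plants stay open.

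Both well-watered Vandana arrays also had loci at the level of Wayrarem. At loci that separated Wayrarem from the other 4 Vandana arrays, replicate 2 had passed the middle of the gap at 50 of 451 (11.1%). The other Vandana arrays, treated alike, had done so at 31 of 433 (well-watered replicate 3), 9 of 425, 2 of 406 and 0 of 394 (drought replicates 1, 2 and 3). Leaving out a well-watered Vandana array leaves 1 of that treatment, so both well-watered values also hold the effect of water. For well-watered replicate 2, 11 neighbouring pairs of such loci were found, against 5.30 on average over shuffles (permutation p = 0.009, adjusted p = 0.045 over 5 arrays). At gaps of 1, 3 and 4 the unadjusted p was 0.001, 0.1 and 0.02, so this rests on the gap taken. Well-watered replicate 3 had 5 such pairs (permutation p = 0.05, adjusted p = 0.12); at a gap of 1 it had more such loci than replicate 2 (112 of 1196 against 94 of 1125) and as many pairs (17 each, permutation p = 0.02), and at gaps of 3 and 4 it had 0 pairs.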
